A study of Mus musculus with 2 samples.

How the data were processed

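RNA was measured on Affymetrix GeneChip Mouse Genome arrays, which carry 45101 probe sets, 64 of them controls. Per the labels' protocols and the series design text, livers of wild-type C57Bl6 embryos at E12.5 were digested with trypsin-EDTA, and mesothelial cells were sorted by FACS with antibodies to Pdpn. Total RNA was taken with RNAqueous Micro, and 20 ng was amplified and labelled with biotin by the NuGEN Ovation systems, per the labels. The labels give 1 array of mesothelial cells and 1 of liver cells, and both were used. A free-text label describes much younger embryos than the stated age, and the stated age was used.

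The deposited values are probe set intensities on a linear scale, judged from the values themselves. The submitters' processing notes name RMA and Partek, with no version, role or order. RMA values are commonly given as log2, and the design had assumed that, so log2 was taken first here. The quantiles of the 2 arrays differ, so they had not been brought to one distribution over these probe sets, and any other scaling is not given in the sources used here. The main values are as deposited, and a scale factor between arrays would move every difference by the same amount. Amplification from 20 ng of RNA can alter the ratios of transcripts, and no second amplification of either sample was analysed here. The file has no detection flags. For precision, the number of arrays is the limit.

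Probe sets were named from the platform annotation, and 34958 had 1 gene symbol, 932 had several and 9147 other than controls had none. Only those with 1 symbol were used. Of these, 34754 matched a gene ID in RefSeq for the GRCm38.p6 assembly, which was used for names only, and 0 were renamed. Positions are not given because the sources used here name no genome build. A gene's value was that of the probe set with the highest mean log2 value over both arrays, which gave 18193 genes, 9010 of them with several probe sets. The SD of the difference between probe sets of one gene is given for some genes, with its number of probe sets. A gene printed without an SD may still have several probe sets. The pooled value, over probe sets above the floor, was 0.70. A gene was above the floor where the higher of its values was at or above the median of all probe sets of its array. Genes above the floor with a difference of at least 1 on the log2 scale were counted.

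Signal over background was judged on 27 probe sets for bacterial transcripts (Dap, Lys, Phe, Thr and Trpn) that read at the bottom of the scale. Where a gene's lower value was within the highest of these on its array, its fold was computed against that level and written as at least N-fold. Such values, for example of Muc16, are bounds, and setting all low values to that level moved no list median by more than 0.27.

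Before the data were examined, 36 gene lists were fixed, and for each the median difference over its measured members was computed. The lists cover mesothelium, coelomic transcription factors, hepatoblasts, hepatocyte secreted proteins, 8 kinds of blood gene (globins, erythroid, haem synthesis, progenitor, megakaryocyte, macrophage, granulocyte and lymphoid), endothelium, lymphatic endothelium, stellate cells, neural cells, striated muscle and gut or pancreas. They also cover epithelial junctions, mesenchymal transition, matrix, retinoic acid, Wnt, Hedgehog, TGF-beta, growth factors, Notch, proliferation, dissociation stress, cholesterol synthesis, interferon, complement, glycolysis, sex-linked genes, reference genes and ribosomal proteins. Each median was placed as a percentile among those of 10000 lists of the same size drawn from genes in the same of 20 bins of mean log2 value, and a list was said to stand apart at or below percentile 0.5 or at or above 99.5. That describes these arrays and is not a test between conditions.

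The genes named were set by a rule fixed at the same time. It takes the 12 genes with the largest difference in each direction above the floor, passing over predicted genes, and in each list up to 4 members with the largest difference and the member furthest the other way. It adds 14 genes in every case, among them Pdpn, Wt1, Msln, Alb and Afp. The rule gave 184 genes, not all of which are printed here. Calb2 was added afterwards as a mesothelial marker under the floor, and some others outside the rule, such as Klf1, Ltf and Prg2, are also printed.

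Alternatives fixed in advance were the median over probe sets, leaving out probe sets with names ending in _x_at or _s_at, centring on the median of all probe sets, centring on reference genes, quantile normalization, no floor, a floor at the 75th percentile, a 4-fold threshold, only members above the floor, and leaving out members of several lists. Added after the data were seen were setting low values to the control level, centring on the hybridisation controls, removing the median difference of those controls, and removing that of the reference genes. Restricting the pooled SD to probe sets above the floor was also decided after values had been seen.

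The calculation was tested on simulated data for the comparison of mesothelial with liver cells, over 18193 genes with 50 planted at each size. Differences were drawn around 0 with the pooled SD of 0.70, independently for each gene. The shift of 0.66 between the deposited arrays was left out, so the shares below do not describe the counts of genes as deposited. Of genes planted at a log2 difference of 1, 48% passed 2-fold, and of those planted at -1, 46%. At 2 and -2 these shares were 90% and 96%. Planted lists of 25 genes fell at percentile 100 or 0. Of 100 lists with no planted difference 1 stood apart, about the share that the cut-offs set for lists drawn at random. Values were computed with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and drawn with matplotlib 3.10.9.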

Results

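Gene expression was measured in cells of the mouse liver at embryonic stage E12.5, when the organ is both a growing epithelium and the main site of blood formation. One array was hybridised with RNA of mesothelial cells, the flat epithelium that covers the organ, which had been sorted by FACS as cells carrying podoplanin (Pdpn) after digestion of the liver with trypsin-EDTA. The other array was hybridised with RNA of liver cells of the same age, and the labels do not say whether cells carrying Pdpn had been removed from them. Each group had 1 array and no replicate, so no difference was tested, and every value describes these 2 arrays only. The median probe set intensity was 65.8 in mesothelial cells and 42.3 in liver cells. The highest of 27 bacterial control probe sets with no matching RNA read 16.2 and 10.5, and 76.8% and 82.4% of probe sets were brighter than that.

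The comparison asked which genes set the mesothelial cells apart from the liver cells around them. Of 12018 genes above the intensity floor, 5457 were at least 2-fold higher in mesothelial cells and 460 were at least 2-fold higher in liver cells. Among 36 gene lists, those of mesothelial markers and matrix proteins had the highest medians, and those of granulocyte and erythroid genes the lowest. Differences are given as log2 intensity in mesothelial cells minus that in liver cells. The median over all 18193 genes was 0.66, so that the typical gene read 1.58-fold brighter on the mesothelial array, and differences of gene lists are therefore also given relative to this median. The share of differing genes that were higher in mesothelial cells was 92.2% as deposited. It was 72.1% (2867 against 1112 genes) after centring each array on its median, 65.1% (2488 against 1335) after quantile normalization and 59.3% (2251 against 1543) after centring on reference genes. Centring on the hybridisation controls, tried after the data were seen, gave 44.9% (1751 against 2146), which turned the majority. These last 2 settings shift the arrays by the difference of per-array medians, 0.86 for the reference genes and 1.08 for the controls. Removing the median of the paired differences instead, 0.35 and 0.019, was also tried after the data were seen. It gave 84.1% (3829 against 723) for the reference genes and 91.9% (5358 against 475) for the controls. The number of genes in each direction thus depended on the scaling, while 22 of the 36 gene lists kept the sign of their median under every scaling tried, and the other 14 are named as such where they appear. A list's percentile places its median among those of 10000 lists of the same size drawn from genes of like mean intensity, and a list is said to stand apart at or below 0.5 or at or above 99.5. The differences of probe sets for the same gene had a pooled SD of 0.70 over 5323 genes. It compares different probe sets on the same 2 arrays, so it holds no variation between embryos, sorts, amplifications or arrays.

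**Figure D1:**
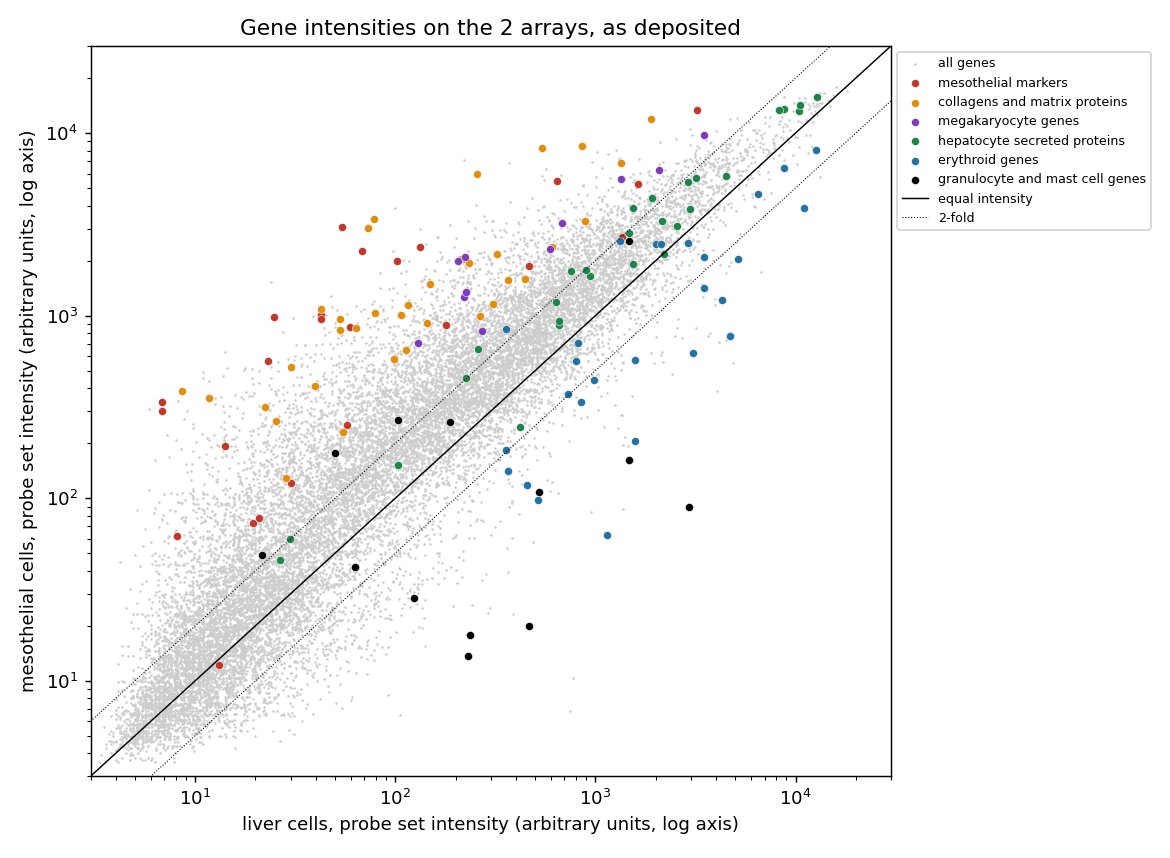
Intensity of each gene in liver cells (x axis) and mesothelial cells (y axis), both in arbitrary units on log axes, with 1 array per axis; each grey point is a gene, coloured points are members of 6 gene lists, the solid line marks equal intensity and the dotted lines 2-fold. Mesothelial, matrix and megakaryocyte genes lie mostly above the upper dotted line, hepatocyte genes near the solid line (median difference 0.67, whose sign turned under other scalings), and erythroid genes and granulocyte and mast cell genes mostly below it.

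Mesothelial genes were the list furthest to the mesothelial side. Of 24 measured markers, 22 were above the floor and 21 of these were at least 2-fold higher in mesothelial cells, with a median difference of 3.43, or 2.76 relative to all genes. Upk3b, a membrane protein of mesothelium and urothelium, read 3053 against 54.4, 56.1-fold higher, with an SD of 0.57 between its 2 probe sets. Muc16, a membrane mucin, and Rspo1, a secreted activator of Wnt signalling, were at control level in liver cells and were at least 32.0-fold and 28.6-fold higher. Aldh1a2, an enzyme that makes retinoic acid, was 39.4-fold higher, the membrane glycoprotein gene Gpm6a 18.0-fold, and the adhesion molecule gene Alcam 4.19-fold. The SD was 0.59 between 2 probe sets for Gpm6a and 0.74 between 5 for Alcam. Gpm6a differed by 3.33 without cross-hybridising probe sets, and the median over the Alcam probe sets was 2.80. Msln, which encodes mesothelin, lay under the floor at 61.8 against 8.1. The other marker under the floor, Calb2, read 12.2 against 13.2 and was thus not higher in mesothelial cells. The keratin gene Krt18, which hepatoblasts also express, had the smallest difference of the markers above the floor, 0.98, and its sign turned under another scaling. Pdpn itself, the gene used for the sort, read 3877 in mesothelial cells, 38.8-fold higher, which checks the labels and is not a finding. Of the 24 markers, 13 also stand in other lists. Without them the median was 4.17. These markers were measured beside 11 of 11 megakaryocyte genes and 10 of 12 muscle genes above the floor that were also at least 2-fold higher in the sorted cells, as given further on.

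Transcription factors of the coelomic epithelium and the septum transversum, the mesenchyme into which the liver bud grows, were also higher in mesothelial cells. Of 18 above the floor, 17 were at least 2-fold higher, with a median of 2.49, or 1.82 relative to all genes. Wt1, required for the development of coelomic epithelia, read 1994 against 102.0, 19.6-fold higher. The nuclear receptor gene Nr2f1 was 19.1-fold higher and the LIM homeobox gene Isl1 14.6-fold, and the basic helix-loop-helix gene Hand2 was 19.4-fold higher with an SD of 1.63 between its 3 probe sets. Lhx9 differed by 0.80, a sign that turned under another scaling, and its other probe sets reached 4.99. Epithelial junction and keratin genes went the same way, with 16 of 22 above the floor at least 2-fold higher and a median of 1.78, or 1.12 relative to all genes. Krt7 was 23.6-fold, Krt19 14.7-fold and the desmosomal cadherin gene Dsg2 12.3-fold higher, the last with an SD of 1.14 between 6 probe sets.

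Matrix genes were higher in mesothelial cells without exception among the 36 measured, all at least 2-fold, and all remained so after median centring. Their median was 3.28, or 2.62 relative to all genes. The collagen VI genes Col6a2 and Col6a1 were 43.1-fold and 41.5-fold higher, the first with an SD of 0.04 between its 2 probe sets. Col4a6, a basement membrane collagen, was at least 37.0-fold higher, and Col12a1 30.4-fold higher with an SD of 2.52 between 4 probe sets. The smallest difference was that of Col4a1, 3.58-fold. Mesenchymal genes stood beside the epithelial ones: all 17 mesenchymal transition genes above the floor were at least 2-fold higher, with a median of 2.30, or 1.63 relative to all genes. The matrix protease gene Mmp2 was 22.3-fold, the cadherin gene Cdh11 10.9-fold and the transcription factor gene Twist2 9.52-fold higher, and Zeb1 was 2.33-fold higher. Genes of stellate and submesothelial cells, the perisinusoidal and subcapsular mesenchyme, were at least 2-fold higher for 22 of 24 above the floor, with a median of 2.14, or 1.48 relative to all genes. The receptor gene Pdgfra was 9.03-fold higher, with an SD of 0.23 between 3 probe sets. The intermediate filament gene Des was 5.25-fold higher and Colec11 9.87-fold, with SDs of 0.89 and 1.03 between 2 probe sets each. Acta2, smooth muscle actin, read 6.41-fold higher from a probe set of a kind that can cross-hybridise, while the median over its 3 probe sets was -0.08. Hgf differed by 0.23, a sign that turned under another scaling. Of the 25 stellate genes, 14 stand in other lists too, and without them the median was 1.78, at percentile 97.2, so the list no longer stood apart.

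Genes of several signalling pathways were higher in mesothelial cells, beside the stellate genes above and the muscle and megakaryocyte genes below, so the cells that express them are not settled. Among Wnt genes, 19 of 20 above the floor were at least 2-fold higher, with a median of 2.15, or 1.49 relative to all genes. The receptor gene Fzd8 was 14.3-fold higher, with an SD of 0.78 between 2 probe sets. The ligand genes Wnt9a and Wnt5b were 41.5-fold and 29.0-fold higher, but their probe sets differed, with SDs of 3.31 and 2.19. All 10 Hedgehog genes above the floor were at least 2-fold higher, with a median of 2.78, or 2.11 relative to all genes. These included the pathway's transcription factors Gli2, 23.8-fold with an SD of 0.72 between 2 probe sets, and Gli1, 12.9-fold, and its co-receptor Gas1, 16.6-fold with an SD of 1.05 between 3. The receptor and target gene Ptch1 was 2.42-fold higher. TGF-beta and BMP genes were at least 2-fold higher for 24 of 25, with a median of 1.96, or 1.30 relative to all genes. Tgfb3 was 25.5-fold, Bmp4 9.07-fold and Gdf10 9.01-fold higher, while Bmp2 differed by 0.83, a sign that turned under another scaling. Growth factor genes were at least 2-fold higher in mesothelial cells for 26 of 29 and in liver cells for 1, with a median of 2.07, or 1.40 relative to all genes. The platelet-derived growth factor genes Pdgfc and Pdgfa were 14.3-fold and 9.40-fold higher, with SDs of 0.20 and 1.23 between 2 probe sets each, and midkine (Mdk) was 8.96-fold higher. The exception, the oncostatin M receptor gene Osmr, was at least 2.69-fold higher in liver cells, but the median over its 3 probe sets was 0.86.

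Most retinoic acid and Notch genes above the floor were also higher in mesothelial cells, but as measured their lists did not stand apart. Of 12 retinoic acid genes above the floor, 9 were at least 2-fold higher in mesothelial cells, and 6 after median centring, with a median of 1.51, or 0.85 relative to all genes, at percentile 96.0. With the median over probe sets the list reached percentile 99.95 and stood apart. Aldh1a1 was 8.18-fold and the binding protein gene Crabp1 7.56-fold higher, and the receptor gene Rara differed by 0.10, a sign that turned under another scaling. Of 11 Notch genes above the floor, 10 were at least 2-fold higher, with a median of 1.31, or 0.65 relative to all genes, at percentile 93.4, and 3 after median centring. Notch3 was 10.3-fold higher, with an SD of 0.41 between 2 probe sets, and the ligand gene Jag1 3.60-fold, with an SD of 0.60 between 3.

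Transcripts of hepatocytes were as bright on the mesothelial array as on the liver array. Albumin (Alb) read 15683 in mesothelial cells and 12832 in liver cells, and alpha-fetoprotein (Afp) 13191 and 10376, differences of 0.29 and 0.35 whose signs turned under other scalings. The median over the 5 probe sets of Afp was 1.24. Over 28 measured genes of secreted hepatocyte proteins the median was 0.67, which also turned sign under other scalings and was 0.00 relative to all genes, at percentile 44.7. Of the 26 above the floor, 5 were at least 2-fold higher in mesothelial cells, and none after median centring. Itih1, Itih2 and Itih3, plasma protein genes of one family, were 2.53-fold, 2.31-fold and 2.33-fold higher, and ceruloplasmin (Cp) read 244.2 against 418.7, with an SD of 1.74 between 8 probe sets. Hepatoblast transcription factor and surface genes had a median of 0.98, with a sign that turned under another scaling, or 0.32 relative to all genes, at percentile 71.7. Of 19 above the floor, 9 were at least 2-fold higher in mesothelial cells, and 3 after median centring, with 3 then at least 2-fold higher in liver cells. Hnf4a, a regulator of hepatocyte identity, was 3.04-fold higher with an SD of 0.51 between 4 probe sets, and the surface gene Dlk1 2.55-fold with an SD of 1.03 between 2.

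The blood lineages went different ways. Erythroid genes were lower in mesothelial cells, with 14 of 27 at least 2-fold higher in liver cells and 1 in mesothelial cells, and 21 and 0 after median centring. The median was -1.14, or -1.81 relative to all genes. The red cell membrane gene Epb42 was 18.3-fold higher in liver cells, with an SD of 0.88 between 2 probe sets, Trim10 7.64-fold and the blood group gene Rhd 6.04-fold. Zfpm1, a cofactor of GATA proteins, was the exception at 2.36-fold higher in mesothelial cells. The other 12 differed by less than 2-fold as deposited, and among them Klf1 still read 2494 against 2899 and Ermap 4646 against 6472. Tfrc, which is also in the reference gene list, read 6467.5 against 8710.4, and the median over its 3 probe sets was -1.07. Erythroid RNA was thus lower in the sorted cells but not absent. Of 8 haem synthesis genes, 3 were at least 2-fold higher in liver cells and 1 in mesothelial cells, and 7 and 0 after median centring, with a median of -0.97, or -1.63 relative to all genes. The erythroid enzyme gene Alas2 was 8.90-fold higher in liver cells, and Alas1, the form of other tissues, 2.48-fold higher in mesothelial cells with an SD of 0.42 between 2 probe sets. Of 4 globins above the floor, 2 were at least 2-fold higher in liver cells, with a median of -0.37 over the 5 measured, or -1.03 relative to all genes. The list stood at percentile 0.42, and at 1.02 by quantile normalization and 0.63 by the median over probe sets, where it no longer stood apart. Without cross-hybridising probe sets its median was -1.53, at percentile 0. The embryonic chain gene Hbb-bh1 was 10.5-fold higher in liver cells with an SD of 0.20 between 3 probe sets, and Hba-x 3.19-fold, whereas Hbb-b2 read 5251 and 5235, a difference whose sign turned under other scalings. Near-identical globin copies share probes, and the single probe set for Hba-a1 read at control level on both arrays.

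Granulocyte and mast cell genes were the list furthest to the liver side, with 7 of 12 above the floor at least 2-fold higher in liver cells and 2 in mesothelial cells. The median was -2.11, or -2.78 relative to all genes, over members from -5.03 to 1.82. It was -1.36 without cross-hybridising probe sets, where the globins lay further to the liver side, and -1.36 without the member of another list. The neutrophil proteins S100a9, Camp and Lcn2 were 32.7-fold, 23.5-fold and 13.2-fold higher in liver cells, and Ngp at least 14.2-fold. The mast cell protease gene Cpa3 was 3.53-fold higher in mesothelial cells. Megakaryocyte genes went the other way from the erythroid genes: all 11 measured were at least 2-fold higher in mesothelial cells, and 8 after median centring, with a median of 2.25, or 1.59 relative to all genes. The platelet glycoprotein gene Gp1bb was 9.60-fold and the signalling gene Rgs18 9.39-fold higher, with SDs of 0.10 and 0.36 between 2 probe sets each, and the integrin gene Itga2b 5.73-fold. Pf4, platelet factor 4, had the smallest difference and read 9712 against 3479.

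The other leukocyte lists did not stand apart, and their medians turned sign under other scalings. Macrophage genes had a median of 0.82, or 0.15 relative to all genes, at percentile 49.3, with 9 of 17 at least 2-fold higher in mesothelial cells and 3 after median centring. Csf1r was 5.47-fold higher with an SD of 1.17 between 3 probe sets, and the scavenger receptor gene Marco 4.60-fold with an SD of 0.01 between 2. Haematopoietic progenitor genes had a median of 0.28, or -0.39 relative to all genes, at percentile 1.97, below the central 95% of drawn lists. Of 13 above the floor, 2 were at least 2-fold higher in mesothelial cells and 1, the transcription factor gene Lyl1, in liver cells, and 1 and 2 after median centring. Lymphoid and pan-leukocyte genes had a median of 0.39, or -0.28 relative to all genes, at percentile 13.9, with 2 of 7 at least 2-fold higher in mesothelial cells and 0 in liver cells, and 1 and 2 after median centring. The pan-leukocyte gene Ptprc (CD45) was one of them at 1.20, but the median over its 2 probe sets was -0.71.

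Blood vessel genes did not separate the arrays. Endothelial genes had a median of 0.74, which turned sign under other scalings, or 0.07 relative to all genes, at percentile 17.4, with 5 of 21 at least 2-fold higher in mesothelial cells and 0 in liver cells, 2 and 2 after median centring, and 0 and 4 by quantile normalization. The receptor genes Stab2 and Tek were 3.45-fold and 2.97-fold higher, and Pecam1 read 84.9 against 102.9. Lymphatic endothelium can also carry Pdpn. Its list had a median of 2.02, or 1.35 relative to all genes, with 5 of 8 at least 2-fold higher in mesothelial cells. With the median over probe sets for each gene the list's median was 0.62, at percentile 30.5, and it no longer stood apart. Nor did it, at percentile 94.6, without members of other lists. Flt4 differed by 2.07 with an SD of 0.10 between 2 probe sets, and Lyve1 differed by 0.15, a sign that turned under another scaling. Of the 9 members measured, 6 stand in other lists.

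Genes of muscle were higher in the sorted cells, and those of other neighbouring tissues were mostly under the floor. Striated muscle genes had a median of 1.93, or 1.27 relative to all genes, with 10 of 12 at least 2-fold higher in mesothelial cells and 1 in liver cells. Cardiac actin (Actc1) was 8.11-fold and the myogenic factor gene Myf5 9.27-fold higher, Tnnt2 19.1-fold and Myod1 6.18-fold, the latter pair with SDs of 1.63 and 1.94 between 3 and 2 probe sets. Acta1 was 2.97-fold higher in liver cells. Of 9 neural and neural crest genes measured, 2 were above the floor. Their median of 0.69 turned sign under other scalings and was 0.03 relative to all genes, at percentile 70.2. Of 15 gut, pancreas and bile duct genes, 3 were above the floor. Their median of 0.81 also turned sign and was 0.15 relative to all genes, at percentile 86.7. Sox9 was 2.83-fold higher in mesothelial cells, but the median over its 3 probe sets was -0.02.

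Genes that cell digestion and sorting can induce were partly higher in mesothelial cells. Of 23 above the floor, 13 were at least 2-fold higher and 1, Ier3, was at least 2-fold higher in liver cells, and 7 and 2 after median centring. The list had a median of 1.19, or 0.53 relative to all genes, at percentile 97.9. With the median over probe sets the list reached percentile 99.8 and stood apart. The heat shock gene Hspa1b, whose near-identical copy shares probes, was 9.78-fold higher with an SD of 1.04 between 3 probe sets, and the immediate early genes Nr4a1 and Atf3 7.81-fold and 6.18-fold. The ratio of signal at the 3' end to that at the 5' end, a sign of RNA length, differed by transcript. It was 2.30 in mesothelial cells and 1.49 in liver cells for Actb, 2.15 and 1.95 for Gapdh, 27.3 and 7.23 for Tfrc, and 4.60 and 9.03 for Pcx.

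Proliferation genes and ribosomal protein genes lay below genes of like intensity. Proliferation genes had a median of 0.01, which turned sign under other scalings, or -0.66 relative to all genes, with 2 of 29 at least 2-fold higher in mesothelial cells and 0 in liver cells, and 0 and 4 after median centring. The mitotic kinase gene Aurka read 642.4 in mesothelial cells and 1209 in liver cells, with an SD of 0.42 between 2 probe sets. The replication genes Cdt1 and Mcm2 differed by 1.06 and 1.01, signs that turned under other settings. Ribosomal protein genes had a median of 0.11, which turned sign under other scalings, or -0.56 relative to all genes, at percentile 0.07. They no longer stood apart by quantile normalization, at percentile 9.92, or by the median over probe sets, at 1.03. One of the 20 passed 2-fold, Rps6, whose 2 probe sets had an SD of 2.28. Reference genes had a median of 0.35, which turned sign under other scalings, or -0.32 relative to all genes, at percentile 8.72, with 1 of 12, Pgk1, at least 2-fold higher in mesothelial cells, and after median centring 0 higher and 1 lower.

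The remaining lists did not stand apart. Complement and innate defence genes had a median of 1.34, or 0.68 relative to all genes, at percentile 93.4, with 9 of 15 at least 2-fold higher in mesothelial cells and 1 in liver cells, and 7 and 1 after median centring. C-reactive protein (Crp) was 5.80-fold and the protease inhibitor gene Slpi 4.96-fold higher there. Cholesterol synthesis genes had a median of 0.99, or 0.33 relative to all genes, at percentile 79.5, with 8 of 16 at least 2-fold higher, and after median centring 0 higher and 1 lower. Glycolysis genes had a median of 0.85, or 0.18 relative to all genes, at percentile 77.9, with 5 of 13 at least 2-fold higher, and after median centring 0 higher and 1 lower. Interferon and antigen presentation genes had a median of 0.42, or -0.24 relative to all genes, at percentile 9.17, with 1 of 11 at least 2-fold higher, and 0 after median centring. The medians of these last 3 lists turned sign under other scalings. Of 4 sex-linked genes the median was 1.34, or 0.67 relative to all genes, at percentile 89.5. Xist, transcribed from the inactive X chromosome of females, read 3483 and 3985, and the Y-linked gene Eif2s3y 1173 and 526.3.

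The genes with the largest differences came from the groups above and from outside them. They were ranked on intensities as read, so the rank of a gene given as at least some fold rests on a value at control level. Beside Upk3b, Muc16, Rspo1, Col4a6, Col6a2, Col6a1 and Wnt9a, the 12 genes furthest to the mesothelial side included nephronectin (Npnt), an integrin ligand, at 64.6-fold with an SD of 1.75 between 5 probe sets. Egfl6, a secreted matrix protein, was at least 29.3-fold higher. Hoxc5 was at least 32.4-fold higher, but another of its 3 probe sets gave a difference of 0.39. The other probe sets of Gpr173 and Efs gave differences of 0.50 and 2.67, against 5.49 for the brightest of each. The 12 genes furthest to the liver side included the stefin genes Stfa2l1 and Stfa3, at least 46.0-fold and 47.8-fold, of a family of near-identical copies whose signals cannot be assigned to one member. Fn3k, which repairs glycated proteins, was 15.7-fold and the interferon-induced GTPase gene Irgm2 11.4-fold higher in liver cells, and Prol1 12.4-fold. The other probe sets of Fn3k and Prol1 gave differences of -2.72 and -2.74, against -3.98 and -3.63 for the brightest of each. Slc5a12 was at least 6.49-fold higher, a bound below the 8.90-fold of Alas2 outside these 12, with an SD of 2.20 between its 2 probe sets, and those of Ccdc92b gave -4.06 and 0.60. S100a9, Camp, Epb42, Ngp and Lcn2 completed these 12.

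By this measure 13 of the 36 lists stood apart on the mesothelial side: the mesothelial, megakaryocyte, lymphatic endothelial, stellate, striated muscle, coelomic, epithelial, mesenchymal transition, matrix, Wnt, Hedgehog, TGF-beta and growth factor lists. Another 6 stood apart on the other side: the globin, erythroid, haem synthesis, granulocyte, proliferation and ribosomal protein lists. Those of the 13 lay at percentile 100, apart from striated muscle at 99.9 and lymphatic endothelium at 99.8, and those of the 6 at 0, apart from globins at 0.42 and ribosomal proteins at 0.07.

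**Figure D2:**
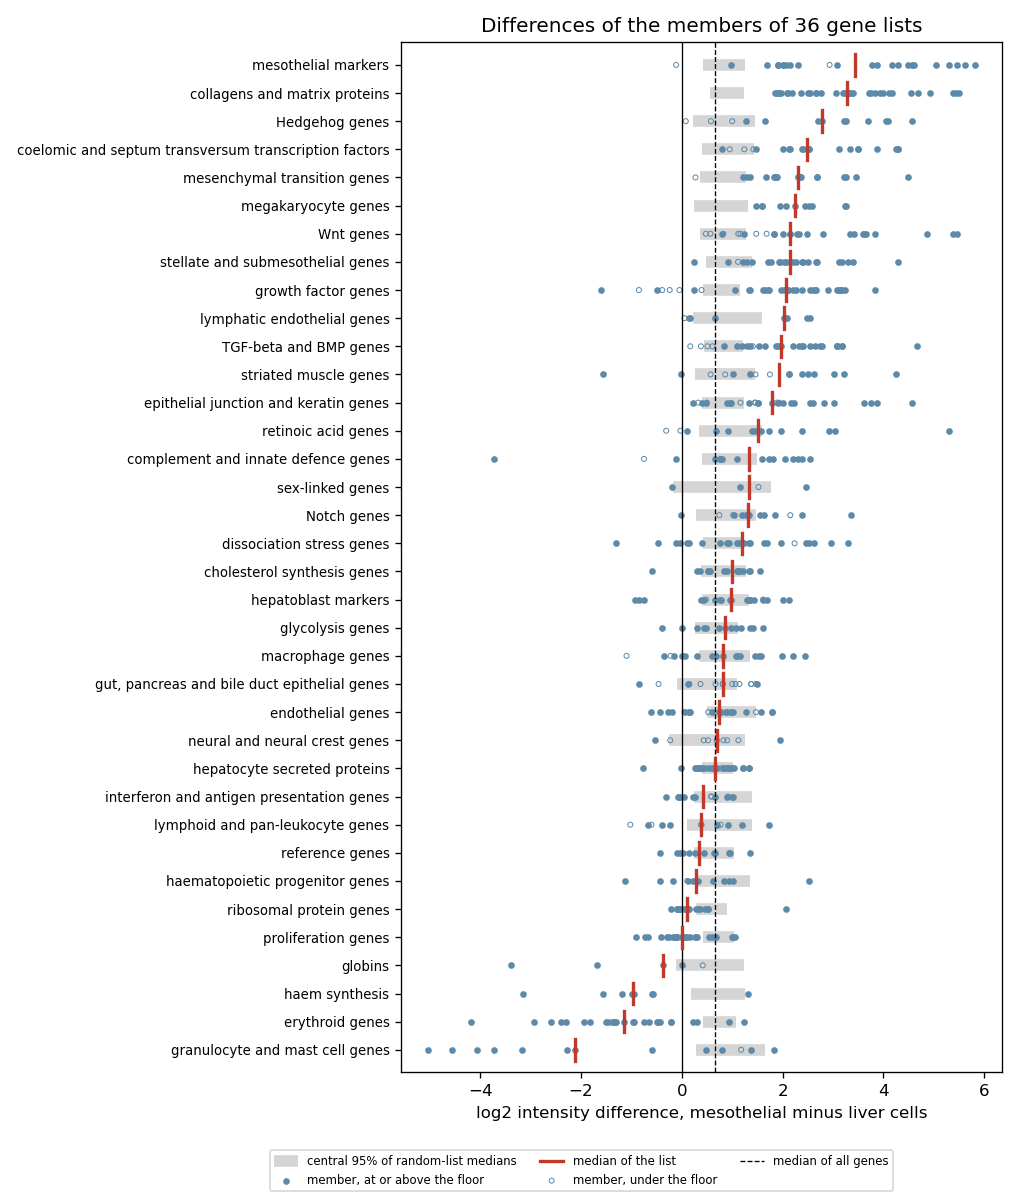
Log2 intensity difference, mesothelial minus liver cells (x axis), of the measured members of 36 gene lists (y axis), with 1 array per group; points are genes, open points lie under the floor, red bars are list medians, grey bars span the central 95% of medians of drawn lists and the dashed line is the median of all genes, 0.66. Medians run from 3.43 for mesothelial markers to -2.11 for granulocyte and mast cell genes, and those of 14 lists turned sign under another scaling.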

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

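Centring on the hybridisation controls, removing their median difference, removing the median difference of the reference genes, and the control level for low values were chosen after the data were seen. Counts and list medians are given where they moved by more than 1.5 times or by more than the pooled SD between probe sets, 0.70, or where a list that stood apart changed sign. The signal over background limits low genes: 76.8% and 82.4% of probe sets were brighter than the highest bacterial control. No sample could be left out, with 1 array per group, and no paired analysis was possible because no test was run.

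Scaling had the widest effect, by construction, since it moves all differences together or by intensity. The counts of genes higher in mesothelial and in liver cells, 5457 and 460 as deposited, were 2867 and 1112 centred on the median of all probe sets, 2251 and 1543 centred on the reference genes, 2488 and 1335 by quantile normalization, and 1751 and 2146 centred on the hybridisation controls. This last setting was the first version run on those controls. It shifts the arrays by 1.08, the difference of the per-array medians, whereas the median of the paired differences is 0.019. The paired version was added once the reversal of the majority had been seen, and gave 5358 and 475. Removing the median difference of the reference genes gave 3829 and 723. Without a floor there were 6584 and 756 of 18193 genes, and with the floor at the 75th percentile 3278 and 185 of 7649, since the floor sets how many genes are counted. At 4-fold there were 1915 and 129 of the same 12018 genes, since fewer pass the higher threshold. The median over probe sets (4137 and 404), leaving out cross-hybridising probe sets (5060 and 464) and the control level (5461 and 461) kept the counts within 1.5 times.

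Centring on the reference genes takes 0.86 from every difference, the difference of their per-array medians, whereas the median of their paired differences is 0.35. The list medians were then 2.57 for mesothelial, 0.12 for hepatoblast, -0.19 for hepatocyte, -1.23 for globin, -2.0 for erythroid, -1.83 for haem, -0.58 for progenitor, 1.39 for megakaryocyte and -0.043 for macrophage genes. They were -2.97 for granulocyte, -0.47 for lymphoid, -0.12 for endothelial, 1.16 for lymphatic, 1.29 for stellate, -0.17 for neural, 1.07 for muscle, -0.044 for gut and 1.63 for coelomic genes. They were 0.92 for epithelial, 1.44 for mesenchymal, 2.42 for matrix, 0.65 for retinoic acid, 1.30 for Wnt, 1.92 for Hedgehog, 1.10 for TGF-beta, 1.21 for growth factor and 0.45 for Notch genes. They were -0.85 for proliferation, 0.33 for stress, 0.13 for cholesterol, -0.44 for interferon, 0.48 for complement, -0.012 for glycolysis, 0.48 for sex-linked, -0.51 for reference and -0.75 for ribosomal genes.

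Centring on the hybridisation controls gave, in the same order, 2.35, -0.092, -0.41, -1.44, -2.22, -2.04, -0.80, 1.18 and -0.26 for mesothelial to macrophage genes. It gave -3.19, -0.69, -0.34, 0.94, 1.07, -0.38, 0.86, -0.26 and 1.41 for granulocyte to coelomic genes. It gave 0.71, 1.22, 2.21, 0.44, 1.08, 1.70, 0.89, 0.99 and 0.24 for epithelial to Notch genes. It gave -1.07, 0.12, -0.084, -0.66, 0.27, -0.23, 0.26, -0.73 and -0.97 for proliferation to ribosomal genes. It also turned the signs of Hlf (-0.064), Cdt1 (-0.012), Mcm2 (-0.065) and Oas1a (-0.063).

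Quantile normalization gave 0.27 for hepatoblast, -1.93 for erythroid, 1.5 for megakaryocyte, -0.025 for macrophage, -0.026 for endothelial, 1.24 for lymphatic, 1.40 for stellate, 1.73 for coelomic and 1.0 for epithelial genes. It gave 1.47 for mesenchymal, 2.48 for matrix, 0.76 for retinoic acid, 1.41 for Wnt, 1.15 for TGF-beta, 1.25 for growth factor, 0.44 for stress, 0.25 for cholesterol and 0.51 for complement genes. Proliferation genes read -0.72 and ribosomal genes -0.16, the latter at percentile 9.92 and so no longer apart. These 2 lists also changed sign centred on the median of all probe sets (-0.63 and -0.53) and with the median difference of the reference genes removed (-0.34 and -0.24). Proliferation genes, at 0.01 as deposited, were -0.011 with that of the hybridisation controls removed, -0.048 by the median over probe sets and -0.11 without cross-hybridising probe sets.

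Choices of probe set and member moved fewer lists. The median over probe sets gave 0.62 for lymphatic genes and turned the signs of Ptprc (-0.71), Sox9 (-0.019), Osmr (0.86), Pfkp (-0.37) and Acta2 (-0.076). Without cross-hybridising probe sets globins were -1.53 and granulocyte genes -1.36, and Mcm2 (-0.15) and Acta2 (-0.076) changed sign. The globin median was then the value of Hbb-y, -1.53 in place of -0.37. The granulocyte list then held 12 members, as it did without the member of another list. Its middle lay between Ltf at -2.11 and Mcpt8 at -0.60 in both cases. Why probe sets of one gene differ was not tested. Without members of several lists, mesothelial markers were 4.17 and granulocyte genes -1.36. The lists whose standing apart changed with a setting were those of globins, lymphatic endothelium, stellate cells, retinoic acid, stress and ribosomal proteins, with the values given in the report. The list medians moved by no more than 0.70 with only members above the floor or with low values at the control level.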

Other observations

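The gene families in these first 3 paragraphs were chosen after their values were seen. Hox genes, which encode position along the body axis, were higher in mesothelial cells: all 14 above the floor, of 33 measured, were at least 2-fold higher, with a median difference of 3.15 over those 14 and 1.41 over all 33, or 2.49 and 0.75 relative to all genes. Several of them, such as Hoxa2 at 85.9 against 7.5, passed the floor through the mesothelial array, so the floor itself favours genes higher there. Hoxb3 read 1117 against 96.8 and Hoxc4 1406 against 92.6, while the 19 others were under the floor on both arrays. Counts in this and the next 2 paragraphs stand beside the 5457 of all 12018 genes above the floor that were at least 2-fold higher in mesothelial cells as deposited. Guidance genes followed: of 29 semaphorin, plexin, Slit and Robo genes above the floor, 23 were at least 2-fold higher in mesothelial cells and 0 in liver cells. Over the 37 measured the median was 1.82, or 1.15 relative to all genes. Sema3d was 22.5-fold and Slit2 7.13-fold higher. Of 14 ephrin and Eph receptor genes above the floor, 13 were at least 2-fold higher in mesothelial cells and 1, Epha5, was 6.71-fold higher in liver cells. Over the 21 measured the median was 1.98, or 1.32 relative to all genes.

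Of 25 matrix metalloproteinase, Timp and Adamts genes above the floor, 20 were at least 2-fold higher in mesothelial cells, among them Adamts9 at 3879 against 455.8 and Timp3 at 1950 against 305.8. Mmp3 and Mmp20 were 4.32-fold and 3.49-fold higher in liver cells. Over the 35 measured the median was 1.72, or 1.05 relative to all genes.

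All 7 genes of a late neutrophil group, which adds Pglyrp1 to members of the granulocyte list, were at least 2-fold higher in liver cells. Their median was -3.73, or -4.39 relative to all genes. Prg2, an eosinophil granule gene in neither group, read 108 against 521.3. A group of 5 genes expressed in earlier myeloid cells adds Ms4a3 to members of the granulocyte list. Of these, 4 were above the floor and none was higher in liver cells by 2-fold. Their median was 1.18, or 0.51 relative to all genes, at percentile 71.8, and Mpo read 2552 in mesothelial cells and 1477 in liver cells. All 6 genes of skeletal muscle formation, from progenitors to fusing cells, were at least 2-fold higher in mesothelial cells, with a median of 3.49, or 2.82 relative to all genes. Myf5, Myod1 and Myog of these also stand in the striated muscle list. The others included Pax7 at 13.6-fold and Mymx at 35.5-fold. For these families the signs of the medians held under each scaling.

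Of the tests that follow, that of abundant transcripts was set before its result was seen, and the others after. Most genes read brighter on the mesothelial array. One scale factor for the whole array would move the hybridisation controls by about 0.66. Their median difference was 0.019, with quartiles from -0.15 to 0.28, although the 4 bioC probe sets differed by 1.33 and the medians of the controls on each array by 1.08. Abundant liver transcripts taking more of the signal would leave a larger share outside the 100 brightest probe sets on the mesothelial array: it was 92.8% against 90.1%, a log2 ratio of 0.043, with 36% of those probe sets on the liver array within 2-fold of its maximum. A larger amount of labelled sample on the mesothelial array, or more RNA species in those cells, may remain, and neither was tested.

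Megakaryocyte genes were higher in the sorted cells. The shift of the whole array is too small for it, since the lowest member differed by 1.48. Blood cells of all kinds carried over would bring erythroid genes, whose median was -1.14, with quartiles from -1.66 to -0.45. These genes thus did not rise with the megakaryocyte genes. The liver at this age is the main site of blood formation, so carried-over blood could hardly raise erythroid genes above their level there. Some stayed bright in the sorted cells, as Klf1 at 2494 against 2899 and Ermap at 4646 against 6472. Carry-over of blood cells is therefore not excluded. Megakaryocytes or platelets among the sorted cells would raise their genes in about one ratio. The 9 members other than Thbs1 and Itgb3, which other cells also express, had an SD of 0.67, against 0.70 between probe sets of one gene, but 8 of the 35 other lists had an SD that small, so this decides nothing. The sort is meant to remove such cells unless they carry Pdpn, but how any of them might pass it was not measured. Megakaryocytes or platelets among the sorted cells and expression by the mesothelial cells themselves cannot be told apart.

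Hepatocyte transcripts were as bright in the sorted cells as in the liver cells. A ceiling of the signal would hide a lower level for bright genes only. The 19 members under an intensity of 3000 in liver cells had a median of 0.81, with quartiles from 0.40 to 1.01. That median was 0.15 relative to all genes and ran from -0.27 to 0.79 under other scalings, so a lower level stays open. Hepatoblasts, or RNA released from them, among the sorted cells would keep hepatocyte genes in one ratio. The 26 members above the floor had an SD of 0.46, under the 0.70 between probe sets, but so did 8 of the 35 other lists, so this decides nothing. Such cells, which the Pdpn sort is meant to remove, and expression by the mesothelial cells themselves cannot be told apart.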
